A study of Mus musculus with 11 samples.

How the data were processed

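Total RNA of mouse lung from littermate controls and Foxa3 knockouts, challenged with saline or OVA, was measured on 11 one-colour (Cy3) Agilent whole-genome arrays. Per the labels, RNA was extracted with RNeasy columns and labelled with a low-input kit. Samples were grouped by genotype and challenge as labelled: 3 wild-type saline, 2 Foxa3 knockout saline, 3 wild-type OVA and 3 Foxa3 knockout OVA arrays. The arrays came from 3 slides and 1 scan date.

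Per the file headers, each scanner file gives for every spot a background-subtracted and detrended intensity from Feature Extraction 9.5.1.1 (the submitters' processing notes name 9.1), with raw spot and local background intensity beside it. The deposited value table holds log2 values: its column medians are 7.669 to 7.674, its sorted columns are nearly equal and its ranks follow the raw median spot signal (rank correlation 0.99992 to 0.99998), so scale, centring and direction could be read from the values, though the labels do not state the method. Each array holds 43379 spots and 41174 probes other than controls, 245 of them in more than 1 spot, and 71.16% to 78.87% of probes were well above background. Saturated spots numbered 0 or 1 per array and uneven spots 48 to 183.

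Intensities were taken as log2 and scaled by subtracting each array's 75th percentile. Probes well above background on at least 2 of 11 arrays were kept: 32946 probes for 21870 genes, 5789 of them with a clone or accession name. Each gene was represented by its brightest probe, and 125 genes lack a value on some array. Names came from a GRCm38.p6 gene table: 23082 probes matched by RefSeq accession, 6582 carried a current symbol, 3073 an older synonym, and 8437 kept the name in the file, since the annotation is old; 378 probes matched several genes. Coordinates are those of the files (mm7).

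One limma model (3.58.1, R 4.3.3) with 1 mean per group was fitted over the 11 arrays with empirical Bayes moderation (prior degrees of freedom 1.95, residual 7), two-sided, with Benjamini-Hochberg adjusted p under 0.05. Contrasts were OVA against saline in each genotype, knockout against wild type after each challenge and over both, and the difference of the OVA effects. 35 gene lists, covering lung and immune cell types, pathways, markers of other tissues and neighbours of Foxa3, were tested with camera (preset correlation 0.01) and again with an estimated correlation and with fry. Of these, 34 had at least 3 measured members. The model, tests, lists, naming rule and alternatives, other than those named as added, were fixed before the data were examined. Genes named are, per comparison, among the 8 largest rises and the 8 largest falls past the threshold with a usable symbol and no overlap between the groups' arrays, and up to 3 members with the smallest p of each list that shifted or had 3 called members; Foxa1, Foxa2 and Foxa3 are always given, and the genes of smallest p where fewer than 4 passed. Where a group lies below background, a change is given as at least the fold to the background limit.

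With 2 or 3 arrays per group, array number limits precision. Tested on simulated data with 21745 genes, the model found 11.9%, 52.2% and 77.3% of 1.5-fold, 2-fold and 4-fold changes for OVA in wild type and 9%, 52.2% and 78.8% for OVA in knockout, with 4 and 6 unchanged genes called. In each simulation 67, 67 and 66 genes changed by these folds, with independent noise and no slide effect. The real OVA comparisons called far more genes and the arrays differ by slide, so the shares from simulated data hold for that setting only. Alternatives were background correction with normexp (offset 50), quantile and median scaling, other filters and probe summaries, only the groups compared, a trended robust prior, array weights, blocks for slide and for replicate number, the authors' value table and each array left out in turn. A model without slide 1 and a normexp fit without spots of far brighter local background were added after seeing the data. A block for scan date was not run, since there is 1 date.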

Results

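The series holds 11 one-colour arrays of total RNA from mouse lung, from littermate controls (called wild type here) and Foxa3 knockouts challenged with saline or with OVA, by background the egg allergen ovalbumin. There are 3 wild-type saline, 2 Foxa3 knockout saline, 3 wild-type OVA and 3 Foxa3 knockout OVA arrays, hybridised on 3 slides. Slides 1 and 2 hold 1 array of each group and slide 3 lacks a knockout saline array, so each comparison could also be made within slides. The first principal component (46.3% of the variance) separated the challenges: saline arrays lie between -59.3 and -45.2 and OVA arrays between 13.2 and 66.2. The second (15.8%) set the 4 arrays of slide 1 (33.8 to 41.9) apart from the other 7 (-29.1 to -16.3), and the third (10.4%) set wild-type OVA 1 (-66.8) apart from the others (-8.5 to 20.9). The p-values measure spread between the samples, since the labels do not say whether each array is 1 animal. Values below are log2 differences with their standard error, and adjusted p is limma's over 21870 genes unless another test is named.

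Foxa3 itself was detected in wild-type lung only and rose with the allergen there. Its probe lay well above background on 6 of 6 wild-type and 0 of 5 knockout arrays. The mean scaled log2 level was -5.94 (SD 0.12, n 3) in wild-type saline, -3.93 (SD 0.07, n 3) in wild-type OVA, -8.53 (SD 0.12, n 2) in knockout saline and -8.41 (SD 0.74, n 3) in knockout OVA. OVA raised Foxa3 in wild type by 2.01 ± 0.30 (4.03-fold, adjusted p 0.00494). By slide the rise was 2.19, 1.98 and 1.86, with adjusted p 0.01 in a fit with slide as a block. In the main fit knockout lung held at least 8.6-fold less after OVA (adjusted p 0.000353, slides -4.66, -3.73 and -5.07, slide block 0.00218). After saline it held at least 1.6-fold less (adjusted p 0.0323, slides -2.54 and -2.58, slide block 0.0623). The slide values run down to the background of the knockout arrays. The call after saline, unlike those after OVA, ended when 1 array was left out: adjusted p 0.111, 0.157 or 0.138 without wild-type saline 1, 2 or 3, 0.275 or 0.204 without knockout saline 1 or 2, 0.0677, 0.0654 or 0.0835 without wild-type OVA 1, 2 or 3, and 0.0671 without knockout OVA 1. Leaving out the whole of slide 1, which leaves 7 arrays, ended all 3 Foxa3 calls, but the effects hardly moved. The rise with OVA was 1.92 (main fit 2.01), and the knockout difference was -4.40 after OVA (main fit -4.49) and -2.58 after saline (main fit -2.60). Slides 2 and 3 were not left out in turn. Planned normexp ended them too (0.60, -1.93 and -1.28, adjusted p 1, 0.635 and 0.789). The rise with OVA and the knockout difference after OVA were much smaller, though still called, with the authors' value table (0.76 and -1.13, adjusted p 0.000752 and 0.000265) and with corrected normexp (0.91 and -1.18, adjusted p 0.000953 and 0.00149). The call after saline was lost with the authors' value table (-0.41, adjusted p 0.362), corrected normexp (-0.22, 0.878) and a trended robust prior (0.0569). A single probe measures Foxa3 (mm7 chromosome 7, 16696078 to 16696137). The labels do not state which part of the gene was deleted, and a probe outside that part would check nothing. The relatives Foxa1 and Foxa2, which act in the same airway cells, did not pass in any comparison. With OVA, Foxa1 was -0.56 in wild type and -0.47 in knockout (adjusted p 0.0729 and 0.187), and Foxa2 was -0.34 and -0.59 (adjusted p 0.151 and 0.0682). Knockout against wild type, Foxa1 was -0.09 after saline and 0.00 after OVA, and Foxa2 was 0.22 and -0.03 (adjusted p 1 in all 4).

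**Figure D1:**
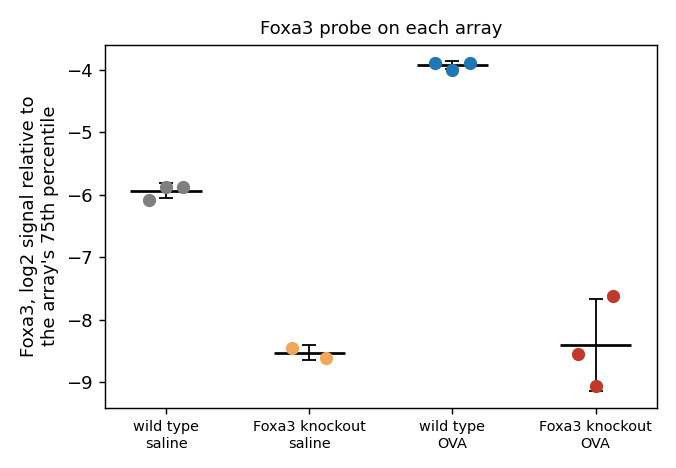
Log2 signal of the Foxa3 probe relative to each array's 75th percentile (y axis) on each of the 11 arrays (points) by group (x axis), with group means (lines) and SD (whiskers). Wild-type means rise from -5.94 to -3.93 with OVA, and the 5 knockout arrays stay at background.

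OVA challenge of wild-type lung raised mucous-cell, macrophage, chemokine, cell-cycle and interferon-response genes. Lists of alveolar type I, airway and endothelial genes shifted down with a minority of their members called. With an estimated correlation 0 of the 34 lists tested passed in this comparison (lowest adjusted p 0.0814, and 0.359 to 0.571 for these resident-cell lists). The largest rises were in Ubd (6.51 ± 0.65), a ubiquitin-like inflammatory gene, the acute-phase gene Saa3 (6.33 ± 0.40), Retnlb (at least 50.2-fold), the chemokine Cxcl9 (6.21 ± 0.29), which attracts activated T cells, and Gdf3 (5.48 ± 0.76). The chemokines Ccl24 (5.42 ± 1.09, an eosinophil attractant), Cxcl10 (5.40 ± 0.29) and Ccl7 (5.32 ± 0.49) rose nearly as far. Adjusted p ran from 0.000124 (Cxcl9) to 0.0147 (Ccl24). Among the largest falls were the fatty-acid binding protein Fabp1 (-3.54 ± 0.81, adjusted p 0.0222, slides -4.04, -1.47 and -5.11), the paraoxonase Pon1 (-2.58 ± 0.55) and the detoxifying Cyp1a1 (-2.31 ± 0.45).

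Of the goblet cell and mucus list, 11 of 12 measured members rose and 0 fell (adjusted over the list alone, 11 up and 1 down). The list median was 1.67 (slides 1.77, 1.45 and 1.30), with camera adjusted p 1.61e-07 and adjusted p = 0.0814 with an estimated correlation. Members that rose include the anion exchanger Slc26a4 (4.24), the mucus lectin Itln1 (3.91) and Agr2 (2.66), which folds mucins. Muc5ac was not measured. In the alternatively activated macrophage list 16 of 17 rose (17 adjusted over the list alone), among them Clec10a (1.77) and the chitinase-like Chil4 (1.99). Its median shift was 1.99 (slides 1.99, 1.44 and 2.57), with camera adjusted p 9.57e-12 and adjusted p = 0.269 with an estimated correlation. Of the type 2 helper T cell list 9 of 15 rose (9 adjusted over the list alone), including Ctla4 (at least 4.0-fold) and Icos (1.54). This list had a median of 1.54 (slides 1.04, 0.74 and 1.96), with camera adjusted p 3.68e-06 and adjusted p = 0.269 with an estimated correlation. Of the T cell list 12 of 16 rose and 1 fell (adjusted over the list alone, 14 and 1), Cd5 by 1.47. Over the list, the median was 1.08 (slides 1.65, 0.70 and 0.76), with camera adjusted p 7.03e-07 and adjusted p = 0.332 with an estimated correlation. The macrophage and monocyte list had 13 of 14 up (13 adjusted over the list alone), with the Fc receptor Fcgr1 (3.09) and the complement gene C1qb (2.74). The list shifted by a median of 1.99 (slides 2.05, 1.32 and 2.54), with camera adjusted p 3.8e-09 and adjusted p = 0.286 with an estimated correlation. Eosinophil markers went both ways: Prg2, a granule protein, rose by 3.03 and Ccr3 by 2.71, while Siglecf, also made by alveolar macrophages, fell by 0.49 (2 up and 1 down of 7, list adjusted p 0.0666, slide block 0.0429).

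Of 27 chemokines, 21 rose (adjusted over the list alone, 23 up and 2 down), with the B-cell attractant Cxcl13 at 4.25. The list median was 2.16 (slides 2.69, 1.94 and 2.52), with camera adjusted p 3.08e-12 and adjusted p = 0.158 with an estimated correlation. All 28 measured cell-cycle genes rose (28 adjusted over the list alone), such as Ccnb1 (2.56) and Birc5 (2.61). Its median shift was 2.21 (slides 2.14, 1.98 and 2.40), with camera adjusted p 1.17e-18 and adjusted p = 0.301 with an estimated correlation. All 19 interferon-response genes rose as well (19 adjusted over the list alone), among them the transcription factor Irf7 (3.45 ± 0.25), the antiviral GTPase Mx1 (3.43 ± 0.25) and Usp18 (2.13 ± 0.17). This list had a median of 2.27 (slides 2.58, 2.17 and 1.92), with camera adjusted p 2.65e-19 and adjusted p = 0.269 with an estimated correlation. Of the dendritic cell and MHC class II list 14 of 16 rose (14 adjusted over the list alone), H2-Ab1 by 1.09. Over the list, the median was 1.09 (slides 1.2, 0.93 and 1.35), with camera adjusted p 1.01e-08 and adjusted p = 0.269 with an estimated correlation. The secretory pathway list had 10 of 21 up (13 adjusted over the list alone), with the chaperone partner Sdf2l1 (1.38) and Ern2 (1.29), a stress sensor of mucous cells. The list shifted by a median of 0.50 (slides 0.34, 0.30 and 0.86), with camera adjusted p 0.000237 and adjusted p = 0.402 with an estimated correlation. In the matrix list 6 of 20 rose and 1 fell (adjusted over the list alone, 9 and 3), Timp1 by 4.33 and Col3a1 by 1.11. The list median was 0.27, with camera adjusted p 0.0346 and adjusted p = 0.402 with an estimated correlation (slide block 0.0596). Smaller upward shifts had few called members. They are natural killer cell (5 of 12, 5 adjusted over the list alone, Klrk1 at 0.85, median 0.44, camera adjusted p 0.00702), B cell (2 of 16, 2 adjusted over the list alone, median 0.72, slides 1.47, 0.24 and 0.29, camera adjusted p 0.00302) and mast cell (1 up and 1 down of 11, median 0.55, 0.0422). Each had adjusted p = 0.402 with an estimated correlation.

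Some lists of resident cells shifted down. The alveolar type II list did not (2 up and 2 down of 16, median 0.01, list adjusted p 0.945), and smooth muscle did not pass (2 down of 13, median -0.25, list adjusted p 0.0575). Of the alveolar type I list 5 of 14 fell (11 adjusted over the list alone, median -0.62, slides -0.73, -0.21 and -0.88, camera adjusted p 0.00021), Clic5 by 0.83. Of the club cell list 5 of 16 fell (7 adjusted over the list alone, median -0.55, slides -0.61, -0.19 and -0.86, camera adjusted p 0.000894), among them Cyp2a5 (-1.89) and Aox3 (-0.91). Both lists had adjusted p = 0.402 with an estimated correlation. The endothelial list had 4 of 16 down (10 adjusted over the list alone), with Tie1 (-0.60) and Pecam1 (-0.45). Its median shift was -0.48 (slides -0.66, -0.23 and -0.55), with camera adjusted p 5.13e-05 and adjusted p = 0.359 with an estimated correlation. Of the xenobiotic list 13 of 22 fell and 4 rose (adjusted over the list alone, 14 and 5): Aldh3a1 fell by 1.68 and Ephx1 by 1.25, while Cyp1b1 rose by 0.76. This list had a median of -0.63 (slides -0.64, -0.37 and -1.04), with camera adjusted p 0.00203 and adjusted p = 0.402 with an estimated correlation. Markers of tissue other than lung airspace fell beside them. Cardiac muscle genes were lower (3 of 14 fell, Myh6 at -1.25; 12 adjusted over the list alone, median -0.98, slides -1.06, -0.71 and -1.19, camera adjusted p 0.000128), as were adipocyte genes (3 of 10 fell, Adipoq at -1.30; 5 adjusted over the list alone, median -0.73, slides -0.73, -0.59 and -1.21, camera adjusted p 0.00267). Both lists had adjusted p = 0.402 with an estimated correlation. Shifts with few or no called members were ciliated cell (0 of 18, median -0.33, camera adjusted p 0.00651, adjusted p = 0.571 with an estimated correlation) and circadian clock (1 down of 16, median -0.55, camera adjusted p 0.0199, adjusted p = 0.269 with an estimated correlation).

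limma called 4110 genes between wild-type OVA and saline, 2381 up and 1729 down (unadjusted p under 0.05 in 7986), of which 1154 rose and 297 fell at least 2-fold. A block for slide called 2734 (1946 up, 788 down), and planned normexp called none. That planned fit was pulled by spots of far brighter local background, 7 on wild-type saline 2 and 5 on wild-type OVA 1. The corrected fit without them called more genes than the main fit. The authors' value table, which differs in background treatment as well as scaling, gave 2418 up and 2679 down. The count was 1531, 1142 and 1972 without wild-type saline 1, 2 and 3, and 6264, 1082 and 1051 without wild-type OVA 1, 2 and 3. Without slide 1 it was 43. The slide block ended the calls of Siglecf (adjusted p 0.055), Clic5 (0.0689) and Myh6 (0.0583). Of the 47 named genes called, 12 lost their call without some 1 array while keeping their direction. With the highest adjusted p and the array left out, these are Clic5 0.136 (wild-type OVA 2), Adipoq and Myh6 0.117 each (wild-type saline 2), and without wild-type OVA 3 Siglecf 0.104, Fabp1 0.0775, Pecam1 and Klrk1 0.0667 each, Pon1 0.0637, Tie1 0.063 and Ccl24 0.053. The others are Cyp1a1 0.0549 (wild-type OVA 2) and Cyp2a5 0.0514 (wild-type saline 2). Of the 22 lists called, 6 did so: mast cell and ciliated cell 0.0999 each (wild-type OVA 2), natural killer cell 0.0786, fibroblast 0.0724 and B cell 0.0618 (wild-type saline 1), and circadian clock 0.056 (wild-type saline 3). Another probe did not pass for Ccr3 and Pecam1, and 1 of 3 for Col3a1 and Clic5, all in the same direction.

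**Figure D2:**
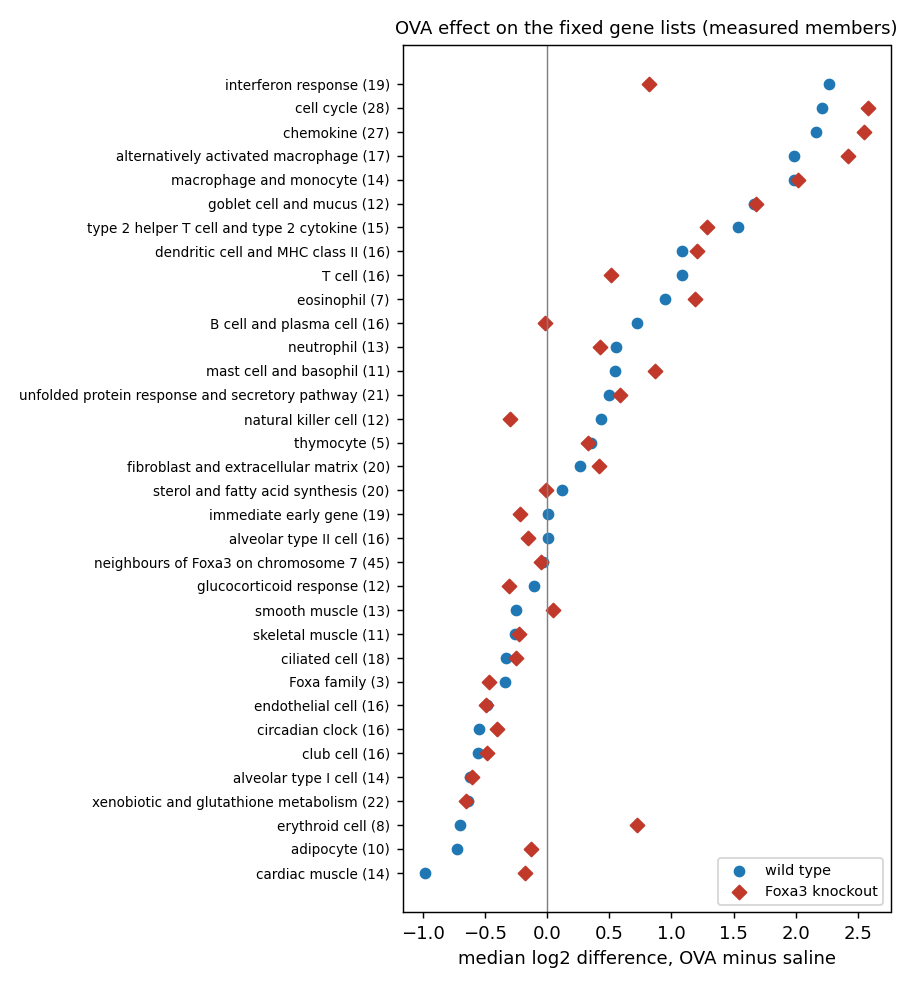
Median log2 difference, OVA minus saline (x axis), of each of the 34 tested gene lists (y axis, with the number of measured members) in wild type (circles) and Foxa3 knockout (diamonds). Cell-cycle medians are 2.21 in wild type and 2.58 in knockout, and interferon-response medians are 2.27 and 0.82.

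Lungs without Foxa3 answered OVA with rises in the same kinds of gene: mucous-cell, macrophage, chemokine and cell-cycle genes. The largest rises were in Ubd (7.05 ± 0.73), Ccl24 (6.70 ± 1.22), Ccl8 (6.25 ± 0.64), Cxcl9 (6.22 ± 0.33), Saa3 (5.92 ± 0.44), Retnlb (5.83 ± 0.89) and Arg1 (5.55 ± 1.32), the arginase of alternatively activated macrophages. Ceacam19 rose at least 15.3-fold, though its other probe did not pass. Fabp1 (-4.30 ± 0.91), the sulfotransferase Sult2a2 (at least 3.1-fold lower) and Pon1 (-2.66 ± 0.61) fell. The slide block ended the calls of Arg1 (adjusted p 0.0896), Fabp1 (0.0685) and Pon1 (0.0866), and of Ephx1 (0.0563) and Pecam1 (0.0653) named below.

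Goblet-cell genes rose without Foxa3: 9 of 12 (11 adjusted over the list alone), with Itln1 at least 21.8-fold higher, Slc26a4 at 5.02 and Agr2 at 3.6. Over the list, the median was 1.68 (slides 1.71 and 1.78), with camera adjusted p 1.85e-09 and adjusted p = 0.0394 with an estimated correlation. Of the alternatively activated macrophage list 14 of 17 rose (16 adjusted over the list alone), with Clec10a at 2.23 and Chil4 at 2.51. The list shifted by a median of 2.42 (slides 2.31 and 2.95), with camera adjusted p 3.88e-14 and adjusted p = 0.25 with an estimated correlation. Of 27 chemokines 19 rose (adjusted over the list alone, 21 up and 1 down). The list median was 2.55 (slides 2.50 and 2.95), with camera adjusted p 2.84e-12 and adjusted p = 0.157 with an estimated correlation. All 28 cell-cycle genes rose again (28 adjusted over the list alone), Ccnb1 by 2.95 and Birc5 by 3.12. Its median shift was 2.58 (slides 2.42 and 3.26), with camera adjusted p 1.74e-23 and adjusted p = 0.268 with an estimated correlation. The macrophage and monocyte list had 10 of 14 up (13 adjusted over the list alone, median 2.02, slides 1.55 and 2.65, camera adjusted p 1.69e-09, adjusted p = 0.268 with an estimated correlation), C1qb by 2.71 and C1qc by 2.44. The dendritic cell and MHC class II list had 13 of 16 up (13 adjusted over the list alone, median 1.21, slides 1.07 and 1.55, camera adjusted p 2.55e-10, adjusted p = 0.25 with an estimated correlation). Of the type 2 helper T cell list 7 of 15 rose (10 adjusted over the list alone), including Icos (1.49) and the IL-33 receptor Il1rl1 (1.29). This list had a median of 1.29 (slides 1.39 and 1.74), with camera adjusted p 9.26e-06 and adjusted p = 0.268 with an estimated correlation. Prg2 rose by 3.83 and Siglecf fell by 0.77.

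Of the interferon-response list 10 of 19 rose (16 adjusted over the list alone), Mx1 by 2.11 and Oas1a by 1.96. Over the list, the median was 0.82 (slides 0.82 and 1.1), with camera adjusted p 4.91e-08 and adjusted p = 0.415 with an estimated correlation. Of the matrix list 8 of 20 rose (adjusted over the list alone, 13 up and 3 down), Timp1 by 4.72 and Col3a1 by 1.52. The list shifted by a median of 0.42 (slides 0.50 and 0.51), with camera adjusted p 0.000179 and adjusted p = 0.25 with an estimated correlation. Of the secretory pathway list 6 of 21 rose and 1 fell (adjusted over the list alone, 14 and 1), Sdf2l1 by 1.49. The list median was 0.59 (slides 0.71 and 0.38), with camera adjusted p 0.000241 and adjusted p = 0.432 with an estimated correlation. T cell genes shifted up (3 of 16 rose, 7 up and 1 down adjusted over the list alone, median 0.52, camera adjusted p 0.00252, adjusted p = 0.545 with an estimated correlation). So did mast cell genes (2 of 11 rose, 4 adjusted over the list alone, median 0.87, camera adjusted p 0.00729, adjusted p = 0.415 with an estimated correlation). Alveolar type I genes shifted down (0 of 14 called, 11 down adjusted over the list alone, median -0.60, slides -0.79 and -0.77, camera adjusted p 4.14e-05, adjusted p = 0.434 with an estimated correlation). Club cell genes were lower too (2 of 16 down, Aox3 at -0.82; 7 adjusted over the list alone, median -0.48, camera adjusted p 0.0018, adjusted p = 0.545 with an estimated correlation), and so were endothelial genes (1 of 16 down, Pecam1 at -0.48; 8 adjusted over the list alone, median -0.49, camera adjusted p 7.62e-05, adjusted p = 0.415 with an estimated correlation). Of the xenobiotic list 7 of 22 fell and 4 rose (adjusted over the list alone, 11 and 5), Ephx1 at -1.2 and Cyp1b1 at 0.88. Its median shift was -0.65 (slides -0.75 and -0.66), with camera adjusted p 0.0249 and adjusted p = 0.545 with an estimated correlation. Cardiac muscle (-0.18, list adjusted p 0.546), adipocyte (-0.13, 0.684) and erythroid markers (0.72, 0.161) did not pass here. Natural killer genes did not pass either (-0.29, 0.163) but were lower with the slide block (-0.41, slides -0.57 and -0.18, adjusted p 0.0146), opposite to wild type. In the main fit with an estimated correlation they passed in neither genotype.

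limma called 1802 genes, 1412 up and 390 down (unadjusted p under 0.05 in 6617), 959 of them at least 2-fold up and 85 at least 2-fold down. The slide block called 849 (788 up, 61 down), and planned normexp called none. The split was 1641 up and 1221 down with the authors' value table and 1447 and 814 with a corrected background fit chosen after seeing the data. The count rests on the 2 knockout saline arrays: it was 83 without knockout saline 1 and 439 without knockout saline 2. It was 1019 and 1122 without wild-type saline 2 and 3, and 3085 and 1107 without wild-type OVA 1 and 3. It was 716, 3308 and 552 without knockout OVA 1, 2 and 3, and 13 without slide 1. Of the 33 named genes called, 22 lost their call without knockout saline 1 (adjusted p 0.0516 to 0.204), 13 of them also without knockout saline 2 (0.0528 to 0.153). Of the 22, 8 lost it without knockout OVA 1 (0.0509 to 0.0918) and 9 without knockout OVA 3 (0.0501 to 0.108), with the direction kept. Arg1 and Pon1 also lost it without wild-type saline 1, 2 or 3 or wild-type OVA 3 (0.0532 to 0.064), Pecam1 without wild-type saline 2 (0.0544), and the xenobiotic list without knockout OVA 1 (0.0789) or knockout saline 1 (0.0598).

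Gene by gene, the OVA effects of both genotypes ran closely together. Called in both were 1540 genes, 1539 in the same direction, with 1225 up against 153.7 from chance and 314 down against 30.8. Those chance numbers take the calls as independent. Both comparisons share each gene's estimate of spread, so the chance numbers may be too low. Across 21870 genes, which are not independent, the OVA effects had Pearson r 0.806 and Spearman rho 0.769. Of the 4110 genes called in wild type, 4055 (98.66%) had the same sign in knockout, with a slope of 0.923. The test of the difference between the responses called 1 probe without a gene name (unadjusted p under 0.05 in 563 genes). That probe differed by -3.58, a size set partly by background, since it lay above background in knockout saline only. The smallest p among named genes belonged to interferon-response genes with lower values in knockout, Irf7 (-2.23 ± 0.37), Ifit1 (-1.82 ± 0.32), Ifi27l2a (-1.33 ± 0.23) and Phf11d (-1.33 ± 0.25). Among higher values it belonged to the lectin Cd209d (1.56 ± 0.27) and Ebf2 (1.14 ± 0.23), and none of these 6 passed (adjusted p 0.828 each). Foxa3 itself (-1.89, with knockout at background) did not pass (adjusted p 1). The interferon-response list was lower in knockout (0 of 19 called, median -1.32, slides -1.44 and -1.02), as was the natural killer list (0 of 12, median -0.66, slides -1.32 and -0.61). Of 34 lists, 14 passed camera and 0 passed with an estimated correlation (lowest adjusted p = 0.131 with an estimated correlation). The call of the single probe ended without every array but wild-type saline 2 and knockout saline 2. In simulated data, this test found 11.9% of 2-fold and 57.6% of 4-fold differences.

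After saline, few genes differed between the genotypes. Besides Foxa3, the largest falls were in Afm, which encodes the vitamin E carrier afamin (at least 29.6-fold lower), Lrmda (-2.22 ± 0.13), Tmem254a (-2.06 ± 0.13), and Plac9a (-2.01 ± 0.11). Smaller falls were in the mitochondrial ribosome gene Mrps12 (-1.2 ± 0.10), Entpd4 (-1.12 ± 0.14) and the laminin receptor Bcam (-1.12 ± 0.13). The rises were in Tescl (3.69 ± 0.21, slides 3.93 and 3.47), Igsf23 (1.69 ± 0.14), the mitochondrial transhydrogenase Nnt (1.26 ± 0.11, 3 of its 4 probes) and the epidermal gene Dmkn (1.17 ± 0.14). Adjusted p of these genes ran from 5.75e-05 (Afm) to 0.0323 (Foxa3). With slide as a block Dmkn (adjusted p 0.144), Entpd4 (0.17) and Bcam (0.0783) lost their calls, as did Foxa3. Plac9a, Tmem254a and Entpd4 have near-identical copies in the mouse genome, by background, so the copy measured is uncertain, and the other Entpd4 probe did not pass.

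Some lists shifted after saline with almost no member called. The cardiac muscle list was lower (0 of 14 called, 7 adjusted over the list alone, median -0.94, slides -1.26 and -0.85, camera adjusted p 5.56e-15), with Mybpc3 at -1.57 and Nppa at -1.69 (adjusted p 0.38 and 0.926). Also lower were erythroid (1 adjusted over the list alone, median -1.1, slides -1.24 and -0.63; 1.3e-06), fibroblast (-0.29, slides -0.31 and -0.29, 7.6e-08; Thbs2 at -0.54, adjusted p 0.609) and smooth muscle markers (3 adjusted over the list alone, -0.15; 1.01e-05). Each of the 4 had adjusted p = 0.199 with an estimated correlation. Adipocyte (3 adjusted over the list alone, median -0.42, slides -0.99 and -0.44, camera adjusted p 0.000186) and mast cell markers (2 adjusted over the list alone, -0.35; 0.00432) were lower too. T cell (0.44, slides 0.99 and 0.31, 1.41e-06; Cd3g at 0.86, adjusted p 1) and sterol synthesis genes (0.18, 0.000139) were higher, and each of these 4 had adjusted p = 0.329 with an estimated correlation. MHC class II genes (median -0.34, slides -0.31 and -0.33, camera adjusted p 1.92e-07, adjusted p = 0.317 with an estimated correlation) and cell-cycle genes (-0.31, slides -0.20 and -0.11, 0.000193, adjusted p = 0.788 with an estimated correlation) were lower. The secretory pathway (0.13, 0.00812, adjusted p = 0.55 with an estimated correlation) and alveolar type II lists (0.10, 0.0132, adjusted p = 0.447 with an estimated correlation) were higher. With fry 0 lists passed after saline. The natural killer list passed with the slide block only (0.15, slides 0.43 and -0.04, adjusted p 0.0273, against 0.06 and 0.632 in the main fit). The interferon-response list did not differ past the test after saline (0 of 19 called, median 0.02, slides -0.10 and 0.11, list adjusted p 0.803).

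limma called 21 genes after saline, 6 up and 15 down (unadjusted p under 0.05 in 713). The slide block called 12 (5 up, 7 down), and planned normexp called none. The split was 11 up and 16 down with the authors' value table and 10 and 13 with the corrected background fit. The count was 11 without wild-type saline 1, 2 or 3 each, and 1 without slide 1. Bcam (adjusted p 0.198), Dmkn (0.281) and Entpd4 (0.274) lost their calls without knockout saline 1, and also without knockout saline 2 (0.151, 0.127 and 0.223) or any 1 wild-type saline array (0.0774 to 0.116). Bcam lost it also without wild-type OVA 3 (0.0527), Dmkn without wild-type OVA 3 (0.0628) or knockout OVA 3 (0.0556), and Entpd4 without any 1 OVA array except knockout OVA 3 (0.0559 to 0.064). Of the 13 lists called, 7 lost their call without some 1 array, here with the highest adjusted p. They are sterol 0.604, secretory pathway 0.415, mast cell 0.131 and cell cycle 0.0524 (knockout saline 1), alveolar type II 0.278 (wild-type saline 1), adipocyte 0.224 and neighbours of Foxa3 0.119 (knockout saline 2). In simulated data, 49.3% of 2-fold and 3% of 1.5-fold differences were found in this comparison.

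After OVA, challenged knockout lung had lower interferon-response genes than challenged wild-type lung. Irf7 fell by 2.45 (SE 0.25, adjusted p 0.00735, slides -2.88, -1.92 and -2.55, slide block 0.0246), Ifi44 by 1.76, Ifit1 by 1.66 and Usp18 by 1.33. Of the list, 6 of 19 fell and 0 rose (18 down adjusted over the list alone). This list had a median of -1.32 (slides -1.64, -0.96 and -1.34), with camera adjusted p 4.1e-45 and adjusted p = 0.107 with an estimated correlation (fry 0.0045). Array means of the list (log2 relative to each array's 75th percentile) were 2.14 to 2.80 in wild-type OVA, 0.84 to 1.21 in knockout OVA and 0.01 to 0.27 in saline arrays (exact two-sided permutation p 0.1, the smallest 3 against 3 can give). Natural killer genes were lower (0 of 12 called, 10 adjusted over the list alone), with the receptor Klre1 at -0.97 and the pore-forming Prf1 at -0.70 (adjusted p 0.0596 and 0.292). Over the list, the median was -0.62 (slides -0.82, -0.59 and -0.41), with camera adjusted p 1.17e-14 and adjusted p = 0.14 with an estimated correlation (fry 0.0437). The goblet cell list did not differ past the test (median 0.18, slides 0.15, 0.19 and 0.08, list adjusted p 0.155).

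Of the 21 genes called after saline, 18 were called after OVA too, those in the same direction (5 up, 13 down), and 20 of the 21 had the same sign. Afm was at least 23.9-fold lower, Lrmda fell by 2.44, Plac9a by 1.82 and Tmem254a by 1.76, while Tescl (3.67 ± 0.19), Igsf23 (1.94 ± 0.13), Nnt (1.24 ± 0.09, 3 of 4 probes) and Dmkn (1.19 ± 0.13) rose. Called here only were rises in the bactericidal Pglyrp1 (2.01 ± 0.22), Pisd-ps3 (2.20 ± 0.23), Camk2b (1.55 ± 0.21) and Zfp420 (1.11 ± 0.16; its other probe was at -0.03), and a fall in the complement receptor C5ar2 (-2.02 ± 0.25). The test of the difference between challenges called none of these 5. The slide block ended the calls of Camk2b (adjusted p 0.101), Zfp420 (0.0552) and C5ar2 (0.0611), and of the interferon-response gene Usp18 (0.0515). Another probe of Ifi44 and of Pisd-ps3 did not pass. Smaller list shifts were lower MHC class II (median -0.19, camera adjusted p 0.00295, adjusted p = 0.793 with an estimated correlation) and immediate early genes (-0.19, 0.0251, adjusted p = 0.14 with an estimated correlation). Secretory pathway (0.18, 0.0141) and xenobiotic genes (0.14, 0.0251, slide block 0.0516) were higher, both with adjusted p = 0.793 with an estimated correlation. The sign of the MHC class II, secretory pathway and xenobiotic shifts differed between slides. The Foxa family list had a median of -0.03 and a mean of -1.50, which is Foxa3 itself (camera adjusted p 0.0141, adjusted p = 0.14 with an estimated correlation).

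limma called 46 genes after OVA, 12 up and 34 down (unadjusted p under 0.05 in 1091). The slide block called 24 (7 up, 17 down). With planned normexp the split was 0 up and 1 down. Corrected normexp, the authors' value table, a trended robust prior and array weights each called more genes than the main fit. The count was 22 without knockout saline 1 or 2 each, and 17 and 29 without wild-type OVA 2 and 3. It was 18, 19 and 27 without knockout OVA 1, 2 and 3, and 1 without slide 1. Of the 18 named genes called, 8 lost their call without wild-type OVA 2 (adjusted p 0.0524 to 0.128): C5ar2, Camk2b, Dmkn, Ifi44, Ifit1, Pglyrp1, Usp18 and Zfp420. Of these, 6 lost it also without knockout OVA 1 (0.0682 to 0.157), 6 without knockout OVA 2 (0.0836 to 0.214) and 5 each without knockout OVA 3 (0.0677 to 0.11) and knockout saline 1 or 2 (0.0526 to 0.0925). It was lost by 4 without wild-type OVA 1 (0.0528 to 0.0741), 3 each without wild-type OVA 3 (0.0653 to 0.135) and wild-type saline 2 (0.0527 to 0.0957), and 2 each without wild-type saline 1 (0.0589 to 0.0626) and 3 (0.0506 to 0.0748). The interferon and natural killer lists kept their calls without any 1 array, while the other 6 did not. Their highest adjusted p and array are xenobiotic 0.807 and MHC class II 0.456 (wild-type OVA 2), secretory pathway 0.375 (wild-type OVA 3), immediate early 0.168 (knockout OVA 3), neighbours of Foxa3 0.131 (knockout OVA 1) and Foxa family 0.0819 (wild-type OVA 1). The simulated data gave a recovery of 50.7% of 2-fold and 6% of 1.5-fold differences here.

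**Figure D3:**
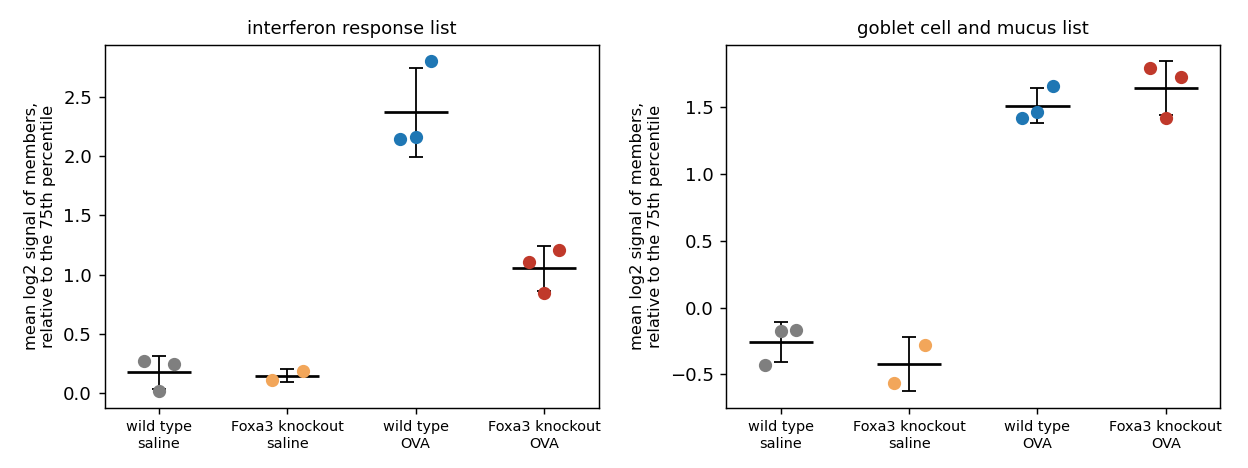
Mean log2 signal of the members of the interferon-response and goblet cell lists, relative to each array's 75th percentile (y axis), for each array (points) by group (x axis), with group means (lines) and SD (whiskers). Interferon means are 2.14 to 2.80 in wild-type OVA and 0.84 to 1.21 in knockout OVA, with no overlap.

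Taken over both challenges, many of the genes that differed between the genotypes lay around Foxa3 on chromosome 7. Leaving out Foxa3 itself, of 58 called genes with an mm7 position 29 (50%) lie within 20 Mb of the Foxa3 probe, 11 higher and 18 lower in knockout, against 505 of 21470 tested genes (2.35%, Fisher's exact p 4.26e-32). They include Tescl (3.68 ± 0.14), Igsf23 (1.81 ± 0.10), Pglyrp1 (1.66 ± 0.16), Rhpn2 (1.19 ± 0.13), Bcam (-0.93 ± 0.09), Irf2bp1 (-0.81 ± 0.09), C5ar2 (-1.66 ± 0.19) and Nfkbid (-1.82 ± 0.24). The 20 Mb window was chosen after the data were seen. Fisher's test takes genes as independent, which linked genes may not be, so its p does not measure spread between samples. Of the fixed list of 45 measured neighbours of Foxa3, taken from GRCm38.p6 gene order, 1 rose and 6 fell (adjusted over the list alone, 4 and 10). The list shifted by a median of -0.05, with camera adjusted p 0.0144 and adjusted p = 0.252 with an estimated correlation (fry for change in either direction 1.15e-08). This list passed camera after saline (0.0218, slide block 0.0724, adjusted p = 0.199 with an estimated correlation) and after OVA (0.0237, slide block 0.056, adjusted p = 0.14 with an estimated correlation). Called genes elsewhere include 9 on chromosome 14, among them Lrmda (-2.33 ± 0.09), Plac9a (-1.92 ± 0.08) and Duxbl1 (lower, and at background in knockout saline). Their probes lie at 20348302 to 23659692 and at 64228669 to 64267881. Those of Entpd4 and of a clone (AK086749) overlap, so the 9 are not all separate loci. Others are Afm (at background in knockout after both challenges), Nnt (1.25 ± 0.07), Camk2b (1.62 ± 0.16) and, on chromosome 7 far outside that window, Irf7 (-1.33 ± 0.18). The interferon-response list was lower over both challenges (1 of 19 called, 17 adjusted over the list alone). The list median was -0.63, with camera adjusted p 2.66e-26 and adjusted p = 0.252 with an estimated correlation. This comes from the OVA arrays, since after saline the list did not differ past the test. In all 14 of 34 lists passed camera over both challenges, 11 lower and 3 higher, and 0 passed with an estimated correlation (lowest adjusted p 0.252). Also lower were cardiac muscle (median -0.51), natural killer cell (-0.27), MHC class II (-0.24), fibroblast (-0.19), erythroid cell (-0.34), mast cell (-0.13), skeletal muscle (-0.08), smooth muscle (-0.06) and the Foxa family (-0.05). Secretory pathway (0.15), T cell (0.15) and sterol synthesis genes (0.13) were higher. Of the 14, 8 lost their call without some 1 array, and the slide block ended those of mast cell (adjusted p 0.0679) and erythroid cell (0.053).

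limma called 66 genes over both challenges, 26 up and 40 down (unadjusted p under 0.05 in 1341). With planned normexp the split was 6 up and 4 down. The slide block called 40 (17 up, 23 down), 39 of them among the 66, and ended the calls of Duxbl1 (adjusted p 0.137), Nfkbid (0.0757) and Irf7 (0.0543). The count was 43 without wild-type saline 2, 33 and 41 without knockout saline 1 and 2, and 4 without slide 1. Without some 1 array, 5 of the 16 named genes called lost their call. With the highest adjusted p these are Duxbl1 0.229 and Rhpn2 0.0515 (knockout saline 1), and Irf7 0.133, Nfkbid 0.0979 and Irf2bp1 0.0611 (knockout saline 2). Within a single challenge the share near Foxa3 was 5 of 16 placed genes after saline (Fisher's exact p 2.49e-05) and 11 of 41 after OVA (1.83e-09). These p-values too take genes as independent.

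**Figure D4:**
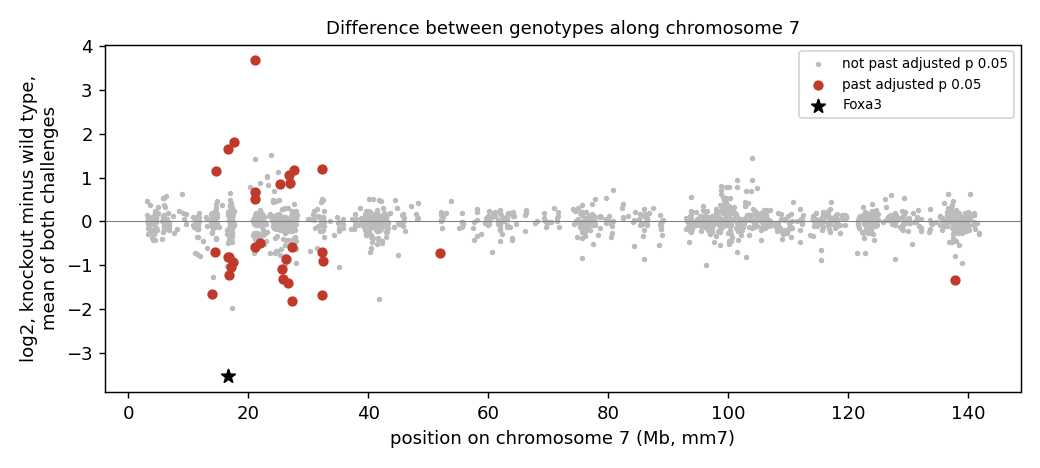
Log2 difference, knockout minus wild type over both challenges (y axis), of tested genes (points) by mm7 position on chromosome 7 in Mb (x axis). Called genes (red) gather around the Foxa3 probe (star), 29 of them within 20 Mb.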

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

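The tests of slides, of single arrays and of leukocyte lists against the interferon difference were chosen only after that difference was seen. Results given here are those where the response to OVA differed between the genotypes by a test of the difference itself, with the sign of knockout minus wild type. One probe without a gene name differed by -3.58, a size set partly by background, since it lay above background in knockout saline only. By list, the median difference was 0.11 for goblet cell and mucus, 0.45 for alternatively activated macrophage, -0.48 for T cell, -0.68 for B cell and plasma cell, -0.66 for natural killer cell, -0.13 for alveolar type II cell, 0.18 for smooth muscle, 0.17 for fibroblast and extracellular matrix, 0.38 for cell cycle, -1.32 for interferon response, 0.71 for cardiac muscle, 0.83 for adipocyte, 1.16 for erythroid cell and -0.25 for the Foxa family. Several of these lists, among them cardiac muscle, adipocyte and erythroid cell, already differed between the genotypes after saline. For them the difference may come from the saline arrays rather than the challenged lung. All 14 lists passed camera with a preset correlation and 0 of the 14 with an estimated one (lowest adjusted p 0.131), and fry called 0. On slides 1 and 2 the sign differed for T cell (-1.32 and 0.05), B cell (-2.00 and 0.29), cardiac muscle (0.84 and -0.10) and erythroid cell (2.46 and -0.42). Without some 1 array 7 of the 14 lost their call, here with the highest adjusted p: alternatively activated macrophage 0.631, cell cycle 0.587, alveolar type II 0.187 and Foxa family 0.187 (wild-type OVA 1), B cell 0.525 (wild-type saline 1), goblet cell 0.098 (knockout OVA 3) and adipocyte 0.0501 (knockout saline 2); with the slide block the alternatively activated macrophage list reached 0.0664.

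Interferon-response genes were lower in challenged knockout than in challenged wild-type lung, which rests on 1 separation of 3 against 3 arrays (permutation p 0.1, the smallest possible, and list adjusted p 0.107 with an estimated correlation). The tables argue against a difference between slides, since the median was -0.96 on the slide where it was weakest, and against a single aberrant array, since it was -1.15 at its weakest with 1 of the 6 arrays left out. The lowest median of the 4 leukocyte lists over all slides was -0.19. This cannot decide whether leukocytes were fewer, since the medians on slide 2 went the other way. T cell medians were -0.36, 0.29 and -0.13 on slides 1, 2 and 3, where interferon genes were -1.64, -0.96 and -1.34. Macrophage, MHC class II and eosinophil medians were -0.43, -0.32 and -0.03 on slide 1 and -1.17, -0.62 and -0.53 on slide 3. They were higher in knockout on slide 2 (0.94, 0.26 and 1.2), which holds the weakly responding wild-type OVA 1. Fewer leukocytes, and a lower macrophage share on slide 3, stay open, since all 4 lists were lower in knockout on slides 1 and 3. Fewer B cells (a list outside those 4, median -0.54, slides -0.56, -0.13 and -0.77, list adjusted p 0.0531) stay open too. The same holds for fewer natural killer cells (list median -0.62) and fewer plasmacytoid dendritic cells, for which no list was tested. A weaker interferon response of challenged lung without Foxa3 may remain as a hypothesis, and a strain difference on chromosome 7, where Irf7 also lies, was not excluded.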

How the results depend on the processing

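The fits without slide 1 and with a corrected normexp were chosen after seeing the data. Of 87 list shifts and 126 calls of named genes, 78 and 126 kept their direction in every setting run, and 1 and 2 kept their call in every one. Without some 1 array 35 and 51 of them lost their call and 0 changed direction; leaving out a knockout saline array leaves 1, assumed to vary like the other groups. Where a call or direction was lost the cause was not tested unless given. Array number and, for genes such as Foxa3, signal near background limit what can be seen.

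Counts of genes called are in the order OVA in wild type, OVA in knockout, knockout after saline, knockout after OVA and knockout over both challenges. Planned normexp gave 0, 0, 0, 1 and 10, Foxa3 after OVA at -1.93 and all-gene medians of -0.22 (after saline), -0.23 (after OVA) and -0.23 (both). Its fitted background mean was -1002 in wild-type saline 2 and -682.4 in wild-type OVA 1, where 7 and 5 spots have a local background far above their signal (difference as low as -64922 and -63145). Without those spots it was -14.6 and -9.9 and the counts were 5673, 2261, 23, 84 and 70, with an all-gene median of 0.13 for OVA in wild type and Foxa3 after OVA at -1.18. The fit without slide 1 gave 43, 13, 1, 1 and 4 and Foxa3 after OVA at -4.40; it has 7 arrays. Array weights gave 10444, 3522, 54, 100 and 95, and only the groups compared 2038, 444, 10 and 11, with fewer arrays for the spread. A trended robust prior gave 2776 for OVA in knockout and 95 for knockout after OVA, and 2862 and 93 were called from the authors' value table, with Foxa3 after OVA at -1.13. Without a filter on dim probes OVA in knockout called 1185 and the OVA effects correlated at 0.641 across genes. The slide block gave 2734, 849, 12, 24 and 40. The single call of the difference of the OVA effects became 0 under either normexp, quantile scaling, no filter, every probe on its own, the trended prior, array weights, both blocks, the authors' table and the fit without slide 1. Against 87 list shifts called, fry called 40 and camera with an estimated correlation 1. A block for scan date was not run, since all arrays share 1 date.

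With 1 array left out the counts ran from 1051 to 6264, 83 to 3308, 11 to 23, 17 to 35 and 33 to 58, the difference of the OVA effects 0 to 1, Foxa3 after OVA -4.88 to -4.16, the correlation 0.721 to 0.826 and the lists called 81 to 104.

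Whether replicate numbers pair the samples was not settled. With group means removed, arrays of different groups that share a number correlated at a mean of -0.073 (15 pairs) against 0.036 (the other 30). Slide was not held constant in this comparison, so it cannot decide. Pairs on the same slide correlated at a mean of 0.224, against -0.113 for pairs on different slides. A block for replicate number gave 3220, 716, 15, 48 and 40 genes.

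The directions that turned are given here. With planned normexp, over both challenges, smooth muscle was 0.072, fibroblast -0.062, Foxa family -0.149 and neighbours of Foxa3 0.014. Neighbours were 0.002 after saline and -0.003 after OVA with planned normexp, and -0.067 for OVA in knockout without a filter. For OVA in wild type fry gave the neighbours the other direction than camera, with the main-fit median at -0.035. Immediate early genes were -0.014 after OVA with planned normexp. For OVA in wild type they were 0.022 with planned and 0.034 with corrected normexp, 0.012 without a filter, -0.123 with array weights, 0.044 without slide 1 and -0.082 to 0.262 with 1 array left out. Some of these turned in the test's direction only, with the median on the same side. For alveolar type II and OVA in wild type, fry gave the other direction than camera, with the main-fit median at 0.007. The median of that list ran from -0.132 to 0.048 with 1 array left out. Without slide 1 the B cell difference of the OVA effects, -0.68 in the main fit, was 0.153 and the secretory pathway after OVA 0.011. Foxa3 for OVA in knockout, at background, was -0.052 with either normexp, -0.031 with the replicate block and -0.278 to 0.448 with 1 array left out. Foxa1 after OVA was 0.019 with quantile scaling, 0.015 with median scaling, 0.065 with array weights, 0.01 with the authors' table and -0.16 to 0.2 with 1 array left out. Foxa2 after OVA was 0.175 with planned normexp, 0.027 with array weights and -0.191 to 0.079 with 1 array left out. For the difference of the OVA effects Foxa1 was -0.08 without slide 1 and -0.066 to 0.294 with 1 array left out, and over both challenges -0.127 to 0.053.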

Other observations

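The tests of strain DNA, of probe variants and of mixed RNA were chosen only after the results they address were seen; the test of a noisier array and the counts over other splits were not.

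Genes that differ between the genotypes gather near Foxa3 on chromosome 7, at 21.3 times the share of tested genes within 20 Mb, and 13.3 and 11.4 times after saline and after OVA alone. DNA of another strain carried along with the targeted locus is a candidate explanation, and it would account for rises as well as falls (11 and 18). Genes on chromosome 14 (9 called, not all separate loci) and Nnt, of which the strain C57BL/6J is known to carry a deletion, may mark strain background, but this was not tested. They lie off chromosome 7, and with littermate controls DNA carried along with the locus would not account for them. Sequence variants under single probes stay open: of 6 such genes with another tested probe, 4 changed the same way on it with unadjusted p under 0.05. Zfp420 (0.05 there against 1.05) and Catsperg2 (0.08 and 0.29 against -1.41), picked after its values were seen, did not meet this. Whether the genes near Foxa3 changed through its loss or through flanking DNA was not tested, and the design does not separate the deletion from its flanking DNA.

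Wild-type OVA 1 showed a weaker response (13.2 on the first component, against 51.6 and 66.2 in the other wild-type OVA arrays, though knockout OVA 2 was at 13.6), keeping 0.448 of the rise of the other two wild-type OVA arrays on the linear scale (median over 959 genes that rose at least 2-fold in knockout). Mixing with RNA of unchallenged lung would dilute all genes alike if the undiluted profile matched the other wild-type OVA arrays. Goblet genes kept 0.94 of their rise (8 genes, quartiles 0.621 to 1.187). Alternatively activated macrophage genes kept 0.291 (14 genes, 0.209 to 0.499), a gap of 0.649. These are the highest and lowest of the lists looked at, and the others ran from 0.349 (chemokine) to 0.699 (interferon response). The gap argues against mixing alone only under that assumption. An array noisier as a whole is argued against too, since its median deviation over genes without a response was 0.209, 0.7 times the highest of the other 5 challenged arrays (0.211 to 0.297). Other signs of quality point the other way: it had the most uneven spots (183) and missing probes (86) of the 11 arrays, the lowest 75th percentile (log2 9.834) and 5 spots with background far above their signal. A difference between animals in the extent of inflammation may remain and was not tested.

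Other splits of the samples into groups of the same sizes were counted. For OVA against saline in wild type the 10 splits are too few for a share under 0.05. The real split (1 of 10) called 4110 genes in a fit over all 11 arrays and the highest other 0. Each other split mixes OVA and saline arrays within a group, which widens the spread, so that 0 tells nothing about chance. For knockout against wild type after OVA the 10 splits are likewise too few, with 46 genes in the real split (1 of 10) and a highest other of 0. For knockout against wild type over both challenges, 2 of 100 splits, drawn from the 200 within each challenge with the real one included, gave as many as the real one. That share is under 0.05, but these splits ignore slides, so it does not exclude chance. Splits within slides were not counted. The other (610 genes) put the 4 arrays of slide 1 together with knockout OVA 3, which points to a structure of the samples by slide, and the slide block gave 40.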
